A study of Mus musculus with 130 samples.

How the data were processed

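Gene expression was measured in shaved, snap-frozen dorsal skin of 130 mice from a backcross, in which F1 females of a cross between FVB/N females and Mus spretus males were mated to FVB/N males. Every mouse is labelled untreated and was, per the labels, aged to 7 weeks. The labels put 92 mice in telogen, the resting stage of the hair cycle, and 38 in anagen, the growth stage. They do not say how the stage was decided. They also give the sex (70 females, 60 males), a batch named P1 to P4 (34, 33, 32 and 31 mice) and an age from 37 to 48 whose unit is not written. The sample titles carry 4 prefixes (LGX in 57 mice, PLX in 63, PLX-vehicle in 6, NOVA-vehicle in 4), whose meaning is not given in the sources used here.

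Per the labels, total RNA was extracted with Trizol, cleaned on Qiagen columns and turned into biotin-labelled cRNA for an Affymetrix array. The authors processed the arrays with RMA (version not stated), and the deposited values are on a log2 scale, read from their range of 0.43 to 13.803. Array medians ran from 5.481 to 5.745, Pearson's r between arrays from 0.922 to 0.989, and 0 pairs of arrays were identical. Arrays have no read depth. Their number limits the precision, and a small change on an array is a change relative to the other genes on it.

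A batch adjustment is not named in the sources used here, but the values carry the mark of one. With no other term in the model, the 4 batch means of a gene differed by a median of 0.011 (log2), and the smallest unadjusted p of limma's F-test over the batches was 0.717 among all genes. With stage and sex in the model, 11 genes had an unadjusted p under 0.05, against a lowest count of 342 and a median of 844 in 99 redraws of the batch. Batch was kept as a term in every model except where an alternative left it out. Errors do not count any degrees of freedom that such an adjustment would have used.

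Of 35556 probes, 171 had no value in any array and were left out, which left 35385, 0 of them with missing values. Of these, 21201 carried a single gene symbol, 1881 carried several and 12303 none; the last 2 kinds were left out. Symbols were taken from the array's annotation, and 21185 probes were matched to the reference table (GRCm38.p6, used for gene names and gene order alone) by Entrez ID, with 0 symbols updated. Where a gene had several probes (1385 genes), the probe with the highest mean over all mice stood for it, which gave 18810 genes. No gene was filtered for low values. Each mouse carries M. spretus alleles at some of its loci, and which probes match the alleles of both species is not given in the sources used here.

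Differences between groups were tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with terms for stage, sex and batch in all 130 mice. The same fit gave anagen minus telogen and female minus male. Further fits added the stage by sex interaction, the slope on the age label, or the title prefix (PLX minus LGX). Values of p were adjusted by Benjamini and Hochberg over all genes, and a gene was called at an adjusted p under 0.05. A count at 2-fold also needs an absolute log2 difference of at least 1. Errors of differences are limma's standard errors (SE), and ± gives the SD across mice.

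Before the data were examined, 37 gene lists were fixed. They covered the hair follicle (hair shaft keratins, inner root sheath, hair matrix and shaft regulators, dermal papilla, bulge stem cells), signalling (hedgehog, Wnt, BMP), the epidermis (basal, differentiation, wound and stress keratinocyte) and the sebaceous gland. Others held markers of cell types that skin samples contain (melanocyte pigment, adipocyte, brown adipocyte, skeletal muscle, fibroblast and matrix, endothelial, Schwann cell and nerve, T cell, macrophage, antigen presentation and dendritic cell, neutrophil, mast cell, B and plasma cell, erythroid). The rest were cell cycle, fatty acid synthesis, cholesterol synthesis, interferon response, inflammatory cytokines, circadian clock, immediate early, heat shock, oxidative phosphorylation, X genes escaping inactivation and Y genes. Each list was tested with limma's camera, which compares its members with all other genes, at a preset correlation between genes of 0.01 and again with a correlation estimated from the data. Adjustment was over the 37 lists. A list's score in a mouse is the mean over its members of the log2 value minus the gene's mean over all mice.

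The genes named were also set by a rule before the data were examined. For stage the rule took the 12 largest differences in each direction among called genes, with at most 2 genes per symbol stem and no provisional names, for sex 8 in each direction, for the interaction the 5 smallest p, and for age 4 in each direction. Up to 3 called members with the largest difference were added for each list and each of stage and sex. The comparisons, tests, covariates and most alternatives were fixed at the same point. The skeletal muscle score as a covariate, the sex and age comparisons in telogen mice alone, the prefix comparison within each batch, the interaction without anagen mice inside the telogen range of the hair shaft score or with anagen mice left out singly or in pairs of males, the test of prefix calls in a held-out batch, the permutation of list scores by stage, the random gene sets of like mean level, and the look at batch means with no other term were chosen after seeing the data.

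The share of mice in anagen was compared between the sexes with Fisher's exact test (two-sided), with exact Clopper-Pearson intervals at 95%. The age label was compared between the stages by a two-sided permutation test with 100000 resamples. The spread of list scores was compared between stages by 10000 permutations of the stage label on the ratio of SDs, after sex and batch were removed by regression. Relations between scores were given as Pearson's r and Spearman's rho with permutation p, by exact enumeration below 10 mice. Genes at 2 separate levels were those whose residuals from stage, sex and batch split into clusters at least 6 pooled SDs apart, the smaller with at least 25% of the mice. Groups held too many mice for a search for single outlying samples, and replicates were not paired.

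Most alternatives changed a single choice: covariates (age label, title prefix, or neither sex nor batch, which drops both terms at once), batch as a random block (duplicateCorrelation with statmod 1.5.0), females, males or each batch alone, each batch left out, age labels 42 to 44, and mice drawn to equal numbers of both stages within each sex and batch. They also took in quantile normalization of the deposited values, arrays centred on their medians, the 25% of genes with the lowest mean level left out, all probes, the mean of a gene's probes, eBayes with trend and robust set together, arrayWeights, and the set test fry. Files were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and with the R package data.table (version 1.17.8). Plots were drawn with matplotlib 3.10.9.

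The fits were tested on simulated data, in which each gene had its measured mean and independent normal noise of its measured residual SD, and known differences between the real groups were added to 200 of the 18810 genes in each of 12 draws. For stage, 80.7% of differences of 0.25 (log2), 97.9% of 0.5 and 99.5% of 1 were recovered. For the interaction the shares were 12.9%, 67.9% and 95.2%. The share of false calls was 5.28% for stage (2.60% to 11.3% in single draws), 5.17% for sex, 4.88% for the interaction, 4.94% for age and 5.12% for the prefix. The simulated noise was independent between genes, whereas measured genes are correlated. A regrouping of the real mice, given below, called up to 459 genes by the interaction. These shares therefore need not hold for the data.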

Results

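The 130 arrays compare dorsal skin in the resting and in the growing stage of the hair cycle. They come from 92 telogen mice (40 females, 52 males) and 38 anagen mice (30 females, 8 males) of a backcross between FVB/N and Mus spretus. Batch P2 holds no anagen male. All values are deposited log2 values per gene, and differences are on the same scale.

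In anagen skin the genes that build the hair were far higher. Krtap8-1, a keratin-associated protein of the hair shaft, averaged 4.10 ± 1.06 (SD, n = 92) in telogen and 10.87 ± 1.23 (n = 38) in anagen, a difference of 6.65 (SE 0.22). Krt71, a keratin of the inner root sheath, which moulds the growing hair, rose by 6.11 (SE 0.17), or 69.1-fold, and Tchh, which encodes the sheath protein trichohyalin, by 4.94 (SE 0.14), or 30.7-fold. All 45 measured Krtap genes rose, by a median of 4.38, and their median kept its sign under both other scalings of the arrays. Slc26a7, an anion transporter gene, fell by 2.44 (SE 0.19). Pappa2, for a protease that cleaves an insulin-like growth factor binding protein, fell by 1.59 (SE 0.11). Skeletal muscle genes were lower too, such as Atp2a1, the calcium pump of fast muscle fibres (fell by 1.49, SE 0.46), and Ttn, the muscle protein titin (fell by 1.47, SE 0.41). Muscle genes varied together between mice (correlation estimated by camera 0.928), so their decreases are not separate results. The score of the muscle list did not pass by stage (permutation p over the 37 lists = 0.167).

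Among the largest increases were also Krtap7-1 (6.57), Krt25 (5.95), Gprc5d (5.46), Crnn (5.20), Prr9 (4.31), Tchhl1 (4.13), Pinlyp (3.84), Calhm4 (3.75) and Lrrc15 (3.53), all with adjusted p of 1.80e-31 or lower in limma. The largest decreases took in Cyp2e1 (-1.56), Il12rb2 (-1.22), Rdh18-ps (-1.19) and the muscle genes Myl1 (-1.43), Myh1 (-1.28), Tnnc2 (-1.28), Tnnt3 (-1.22) and Pvalb (-1.22). In limma, 3946 genes were higher and 6343 lower in anagen, 10289 of 18810 genes in all (54.7%). The median difference over all genes was -0.04. At 2-fold or more the balance was the other way, with 272 genes higher and 32 lower. Of the 10289 genes, 96.3% had the same sign of difference in females and in males, and the differences of the sexes correlated across all genes at r = 0.921, where genes are not independent replicates. The 10289 were called in both sexes together, which builds in a part of the shared sign. The labels do not say how a mouse's stage was decided. If it was read from expression, the hair genes' difference is partly built into the groups.

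**Figure D1:**
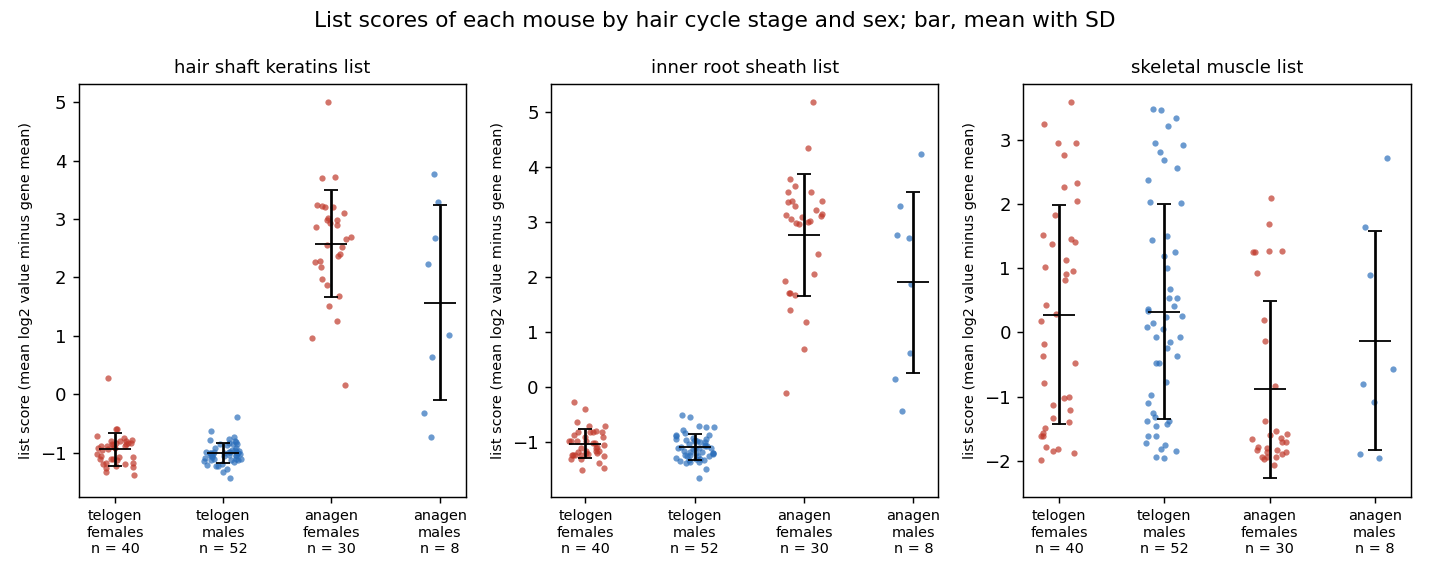
Scores of 3 gene lists (mean log2 value of the members minus each gene's mean over all mice, y axis) for each mouse by stage and sex (x axis), with group mean and SD. The hair shaft list averaged -0.98 in the 92 telogen and 2.37 in the 38 anagen mice, and the skeletal muscle list 0.30 and -0.73 with wide overlap.

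All 12 hair shaft keratins rose, with a median of 3.20 (limma camera, adjusted p = 1.68e-24, and adjusted p = 0.00418 with an estimated correlation). Krt33a rose by 5.40 (SE 0.21), Krt86 by 5.18 (SE 0.18) and Krt31 by 4.45 (SE 0.18). Of 16 inner root sheath genes, 15 rose and 1 fell, with a median of 3.47 (camera, adjusted p = 3.41e-26, and adjusted p = 0.00418 with an estimated correlation), and Krt27 rose by 5.89 (SE 0.17). Among 18 hair matrix and shaft regulators, 13 rose and 2 fell, with a median of 0.56 (camera, adjusted p = 1.14e-08, and adjusted p = 0.17 with an estimated correlation). The transcription factors Elf5 (1.81, SE 0.11), Hoxc13 (1.65, SE 0.092) and Dlx3 (1.44, SE 0.086) led that list. Of 15 BMP signalling genes, 8 rose and 5 fell, with a median of 0.14 (camera, adjusted p = 0.00991, and adjusted p = 0.402 with an estimated correlation). Bambi (1.19), Smad7 (0.84) and Id4 (0.89) were its largest changes, of which Bambi and Smad7 encode inhibitors of TGF-beta family signalling. In the wound and stress keratinocyte list, 9 of 17 genes rose and 1 fell (median 0.38, camera adjusted p = 9.40e-05, and adjusted p = 0.402 with an estimated correlation). They included the antimicrobial peptide gene Defb4 (2.38, SE 0.13), Sprr2h (2.03, SE 0.16) and Krt16 (1.76, SE 0.19). Oxidative phosphorylation genes rose in 10 and fell in 2 of 16 cases, by little (median 0.17, camera adjusted p = 0.0114, and adjusted p = 0.445 with an estimated correlation), with Ndufa1 (0.48), Cox5a (0.48) and Ndufa4 (0.37) in front. Paralogs in the Krtap, keratin and Sprr families share sequence, and a probe can read more than the gene it is named for.

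Camera called the fibroblast, endothelial, macrophage and T cell lists lower in anagen at its preset correlation, and did not call them with an estimated one. Of 19 fibroblast and matrix genes, 17 fell and 1 rose, with a median of -0.43 (camera, adjusted p = 0.00318, and adjusted p = 0.548 with an estimated correlation). Lum, a collagen-binding proteoglycan, fell by 0.88 (SE 0.13) and the collagen cross-linking enzyme gene Lox fell by 0.58 (SE 0.13), while Fn1, for fibronectin, rose by 0.60 (SE 0.082). In the endothelial list, 15 of 18 fell (median -0.28, camera adjusted p = 0.0176, and adjusted p = 0.575 with an estimated correlation), among them Emcn (-0.55), Eng (-0.49) and Ptprb (-0.47). Macrophage genes fell in 15 of 18 cases (median -0.43, camera adjusted p = 0.016, and adjusted p = 0.575 with an estimated correlation), led by the lysozyme gene Lyz2 (-0.80, SE 0.14) with Adgre1 (-0.66) and Lyz1 (-0.63). In the T cell list, 11 of 15 fell (median -0.32, camera adjusted p = 0.0114, and adjusted p = 0.477 with an estimated correlation), with Cd3e (-0.80, SE 0.085) and Cd3g (-0.68), chains of the T cell receptor complex, and Thy1 (-0.68). In the same mice 22 of 24 skeletal muscle genes were lower in anagen (23 adjusted over the list alone), with a median of -0.96, and the list's own test did not pass (camera, adjusted p = 0.0609, and adjusted p = 0.756 with an estimated correlation).

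The dermal papilla list, markers of the mesenchyme that instructs the follicle, had 15 of 20 genes lower and 3 higher (median -0.35, camera adjusted p = 0.0038, and adjusted p = 0.402 with an estimated correlation). Crabp1, which binds retinoic acid, fell by 1.13 (SE 0.087), Notum, an enzyme that inactivates Wnt proteins, fell by 1.07 (SE 0.088) and the leptin receptor gene Lepr fell by 0.95 (SE 0.092). In cholesterol synthesis, 15 of 16 genes fell (median -0.35, camera adjusted p = 8.08e-05, and adjusted p = 0.402 with an estimated correlation), with Lss (-0.57), Hsd17b7 (-0.57) and Mvd (-0.54). Adjusted over the list alone, 1 cholesterol gene was also higher. Sebaceous gland genes fell in 11 of 16 cases and rose in 1 (12 lower adjusted over the list alone), with a median of -0.29 (camera, adjusted p = 0.0186, and adjusted p = 0.477 with an estimated correlation). Awat2 (-0.76, SE 0.18) and Awat1 (-0.57), wax synthesis genes, and Scd3 (-0.57) had its largest decreases. In fatty acid synthesis 10 of 14 fell and 2 rose (median -0.24, camera adjusted p = 0.0315, and adjusted p = 0.445 with an estimated correlation): Acacb (-0.65) and Mlxipl (-0.46) fell and Fads2 (0.42) rose. Circadian clock genes were lower in 12 of 15 cases and higher in 2 (median -0.43, camera adjusted p = 0.0176, and adjusted p = 0.445 with an estimated correlation). Hlf (-0.75, SE 0.067) and Ciart (-0.75, SE 0.076) fell and Nfil3, a repressor that binds the same sites as Hlf, rose by 1.33 (SE 0.066). The time of day of sampling is not given in the sources used here.

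**Figure D2:**
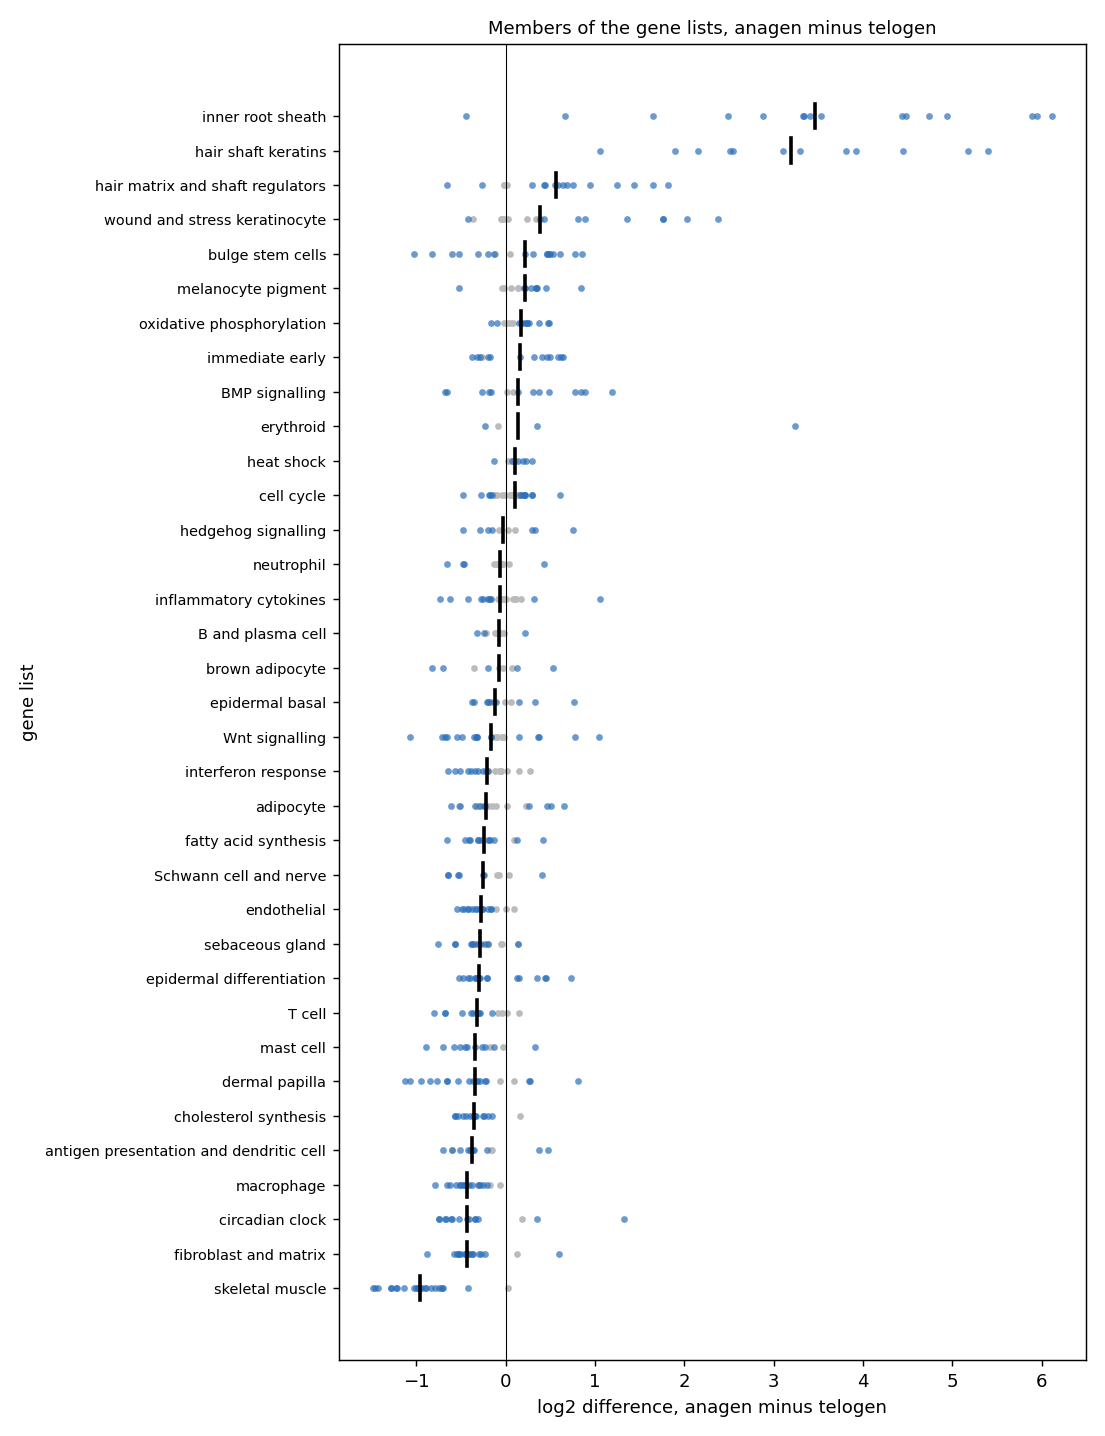
Anagen minus telogen difference (log2, x axis) of each member of 35 gene lists (y axis), each dot a gene, blue at an adjusted p under 0.05 and grey otherwise, with the list's median as a black bar. Hair shaft keratins (median 3.20) and inner root sheath genes (3.47) lie far to the right of all other lists.

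No other list passed camera, though members of many of them changed. Of all genes 54.7% were called by stage, so called members are expected in any list. Melanocyte pigment genes rose in 8 and fell in 1 of 15 cases (median 0.21, adjusted p = 0.0609), with Ednrb (0.84) and Tyr (0.45) higher and Sox10 (-0.52) lower. In the bulge stem cell list 10 of 19 rose and 7 fell (adjusted p = 0.107), with Tbx1 (0.85) higher and Fgf18 (-1.03) and Lgr6 (-0.82) lower. Wnt signalling genes fell in 12 and rose in 5 of 23 cases (adjusted p = 0.135), with Wnt11 (1.04, SE 0.069) and Lgr5 (0.77, SE 0.092) higher beside the lower Notum. Among 10 hedgehog genes 3 rose (4 adjusted over the list alone) and 4 fell (adjusted p = 0.695), with Shh (0.75, SE 0.079) and Gli2 (0.32) higher and Boc (-0.48) lower; the list's median of -0.03 and mean of 0.03 differ in sign, and camera pointed up. Cell cycle genes rose in 8 and fell in 5 of 27 cases (median 0.10, adjusted p = 0.287), with Cenpa (0.61) and Cenpe (0.30) higher and Ttk (-0.48) lower.

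Epidermal differentiation genes fell in 13 and rose in 6 of 19 cases (median -0.30, adjusted p = 0.142), Lce1b (-0.52) and Lce1d (-0.48) down and Rptn (0.73) up. Epidermal basal genes fell in 7 and rose in 3 of 12 cases (median -0.12, adjusted p = 0.96, camera direction up against the sign of the median), with Lamb3 (-0.37) and Dst (-0.36) lower and Cdh3 (0.77) higher. Of 14 antigen presentation and dendritic cell genes 9 fell (11 adjusted over the list alone) and 2 rose (adjusted p = 0.0609), with H2-DMa (-0.71), Ciita (-0.60) and Cd86 (-0.51). Mast cell genes fell in 10 of 13 cases (11 adjusted over the list alone) and rose in 1 (adjusted p = 0.0842), with Cpa3 (-0.89), Mcpt4 (-0.71) and Ms4a2 (-0.58). Schwann cell and nerve genes fell in 6 and rose in 1 of 10 cases (adjusted p = 0.0566), with Cdh19 (-0.65), Ncam1 (-0.65) and Pmp22 (-0.54). Interferon response genes fell in 10 of 18 cases (adjusted p = 0.159), with Usp18 (-0.64), Oas2 (-0.57) and Ifit3 (-0.52). Inflammatory cytokine genes fell in 8 and rose in 2 of 22 cases (adjusted p = 0.666), with Ccl20 (1.05) higher and Il33 (-0.73) and Il1a (-0.63) lower. In the neutrophil list 3 of 13 fell and 1 rose (adjusted p = 0.532), with Mmp9 (-0.66), Mpo (-0.48) and Il1r2 (-0.47) lower. In the B and plasma cell list 2 of 11 fell and 1 rose (adjusted p = 0.574), with Mzb1 (-0.32) and Jchain (-0.24) lower and Ighm (0.21) higher.

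The adipocyte list was split, with 4 of 19 genes higher and 6 lower (adjusted p = 0.527), Fabp4 (0.65) up and Pparg (-0.61) and Plin4 (-0.51) down. So was the brown adipocyte list, with 2 of 9 higher and 3 lower (adjusted p = 0.96), Ppargc1a (0.53) up and Cox8b (-0.83) and Slc27a2 (-0.71) down. With the skeletal muscle score in the model Cox8b went to -0.087 (limma, adjusted p = 0.504), while Ppargc1a (0.60) and Slc27a2 (-0.72) kept their calls. Immediate early genes rose in 8 and fell in 5 of 15 cases (6 lower adjusted over the list alone; adjusted p = 0.053), with Jun (0.64), Egr2 (0.62) and Ier2 (0.59) higher. Heat shock genes rose in 5 and fell in 1 of 9 cases (adjusted p = 0.135), with Bag3 (0.30), Hsph1 (0.23) and Dnajb1 (0.19). In the erythroid list of 4 genes, Slc4a1, the anion exchanger of the red cell membrane, rose by 3.24 (SE 0.13). Alas2 rose by 0.35 and Epb42 fell by 0.23 (adjusted p = 0.179). Of 5 X genes escaping inactivation 2 rose, Kdm5c (0.30) and Ddx3x (0.27), and of 6 Y genes 1 did, Kdm5d (0.14). Neither list passed (adjusted p = 0.185 and 0.641), and the sign of both medians changed when the arrays were rescaled. Fibroblast and matrix genes adjusted over the list alone had 2 higher in place of 1, and for the lists given no such count here and by sex, both adjustments gave equal counts.

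Outside the sex-linked genes, Cyp2g1, for a cytochrome P450, had the largest difference between female and male skin. It averaged 11.29 ± 0.69 (n = 70) in females and 7.57 ± 1.90 (n = 60) in males, a difference of 3.79 (SE 0.26), or 13.9-fold. Carns1, for carnosine synthase, was 2.95 (SE 0.13) higher in females, and Akr1c14 (2.23, SE 0.13) and Akr1c18 (2.08, SE 0.18), both hydroxysteroid dehydrogenase genes, were higher too. Males were higher in Serpinb6c (-1.68, SE 0.14), Aldh1l2 (-1.67, SE 0.086), Cyp2b23 (-1.62, SE 0.15), the imprinted long RNA Meg3 (-1.58, SE 0.081) and Mmp3, a matrix metalloproteinase gene (-1.53, SE 0.12). Cholesterol synthesis genes were lower in females, also with an estimated correlation (camera, adjusted p = 0.000183). The T cell and the antigen presentation lists (adjusted p = 0.21 each) and the fibroblast and matrix list (0.397) were called at the preset correlation and lost their call with an estimated one.

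The sex labels fitted the sex-linked genes. Xist, the RNA that silences an X chromosome, was 7.70 (SE 0.056) higher in females, and the Y genes Eif2s3y (-6.36), Uty (-5.48) and Kdm5d (-3.97) were lower. All 5 X genes escaping inactivation were higher in females (median 0.44, camera adjusted p = 4.38e-41, and adjusted p = 1.97e-20 with an estimated correlation), among them Kdm6a (0.68), Kdm5c (0.44), Eif2s3x (0.44) and Ddx3x (0.24). In the Y gene list 3 of 6 were lower in females (4 adjusted over the list alone; median -2.03, camera adjusted p = 1.77e-54, and adjusted p = 2.99e-24 with an estimated correlation). The probes of Usp9y (-0.06), Zfy1 (-0.09) and Zfy2 (-0.08) showed no called difference at mean levels of 2.86, 2.94 and 4.55 in males. Hamp (1.23), Pi16 (1.14) and the X-linked Firre (1.12) completed the largest female increases. In limma 2851 genes were higher and 1160 lower in females, 4011 in all, of which 12 were higher and 32 lower by 2-fold or more. The balance rested on the scaling: 71.1% of the called genes were higher in females as deposited, 59.7% of 3768 after quantile normalization, and 49.6% of 3593 with arrays centred on their medians.

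Of 16 cholesterol synthesis genes, 14 were lower in females and 0 higher, with a median of -0.34 (camera, adjusted p = 5.75e-28, and adjusted p = 0.000183 with an estimated correlation). Hsd17b7 averaged 9.23 ± 0.54 in females and 10.61 ± 0.43 in males, a difference of -1.23 (SE 0.079), and Lss (-0.80, SE 0.058) and Cyp51 (-0.73, SE 0.061) followed. In the fibroblast and matrix list 8 of 19 were lower and 4 higher (9 and 5 adjusted over the list alone), with a median of -0.15 (camera, adjusted p = 7.21e-07, and adjusted p = 0.397 with an estimated correlation). Its largest differences were the fibrillar collagens Col1a2 (-0.85, SE 0.071), Col1a1 (-0.83, SE 0.061) and Col3a1 (-0.72, SE 0.073). Oxidative phosphorylation genes were lower in females in 8 of 16 cases (9 adjusted over the list alone), with a median of -0.12 (camera, adjusted p = 5.43e-06, and adjusted p = 0.0962 with an estimated correlation), as in Ndufa1 (-0.28), Ndufa4 (-0.27) and Atp5o (-0.19). Sebaceous gland genes were lower in 8 and higher in 2 of 16 cases (median -0.10, camera adjusted p = 0.000965, and adjusted p = 0.35 with an estimated correlation), led by Elovl3 (-0.73, SE 0.083) with Scd3 (-0.31) and Awat1 (-0.30). Epidermal differentiation genes were lower in 6 (7 adjusted over the list alone) and higher in 2 of 19 cases (median -0.08, camera adjusted p = 0.0117, and adjusted p = 0.472 with an estimated correlation), with Krt2 (-0.41), Lor (-0.19) and Calm4 (-0.15). Camera also called the skeletal muscle list lower in females (median -0.17, adjusted p = 0.0458, and adjusted p = 0.723 with an estimated correlation), although 0 of its 24 genes passed in limma and 0 had an unadjusted p under 0.05.

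Lists higher in females included the T cell genes, 10 of 15 higher (11 adjusted over the list alone) with a median of 0.24 (camera, adjusted p = 1.84e-05, and adjusted p = 0.21 with an estimated correlation). Icos, a T cell costimulator gene, was 0.56 (SE 0.075) higher, with Gzmc (0.48) and Il2rb (0.32). Antigen presentation and dendritic cell genes were higher in 11 of 14 cases (12 adjusted over the list alone), with a median of 0.20 (camera, adjusted p = 9.60e-06, and adjusted p = 0.21 with an estimated correlation), among them Xcr1 (0.66, SE 0.11), Flt3 (0.56, SE 0.083) and Cd1d1 (0.48). Dermal papilla genes were higher in 10 of 20 cases (camera, adjusted p = 0.00321, and adjusted p = 0.35 with an estimated correlation), as in Notum (0.68), Alpl (0.52) and Corin (0.49). Adipocyte genes were higher in 11 of 19 cases (13 adjusted over the list alone) and lower in 1 (median 0.30, camera adjusted p = 0.00587, and adjusted p = 0.564 with an estimated correlation), with Cidec (0.91, SE 0.23), Retn (0.79) and Pck1 (0.67). Hair matrix and shaft regulators were higher in 8 of 18 cases (adjusted p = 0.0117, and adjusted p = 0.56 with an estimated correlation), with Hoxc13 (0.38), Elf5 (0.33) and Foxn1 (0.30). Hedgehog signalling was also called (5 of 10 higher, 6 adjusted over the list alone, adjusted p = 0.0362, and adjusted p = 0.472 with an estimated correlation), with Gli2 (0.38), Gli1 (0.20) and Ptch1 (0.17). So was the mast cell list (7 of 13 higher, adjusted p = 0.0362, and adjusted p = 0.56 with an estimated correlation), with Cpa3 (0.70), Mcpt4 (0.64) and Mrgprb1 (0.41). Melanocyte pigment genes were higher in 7 (8 adjusted over the list alone) and lower in 1 of 15 cases (adjusted p = 0.0362, and adjusted p = 0.56 with an estimated correlation), with Tyrp1 (0.44) and Dct (0.43) higher and Mlana (-0.52) lower. Bulge stem cell genes were higher in 9 and lower in 1 of 19 cases (2 lower adjusted over the list alone, adjusted p = 0.0433, and adjusted p = 0.574 with an estimated correlation), with Lhx2 (0.26), Lgr5 (0.23) and Postn (0.23).

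**Figure D3:**
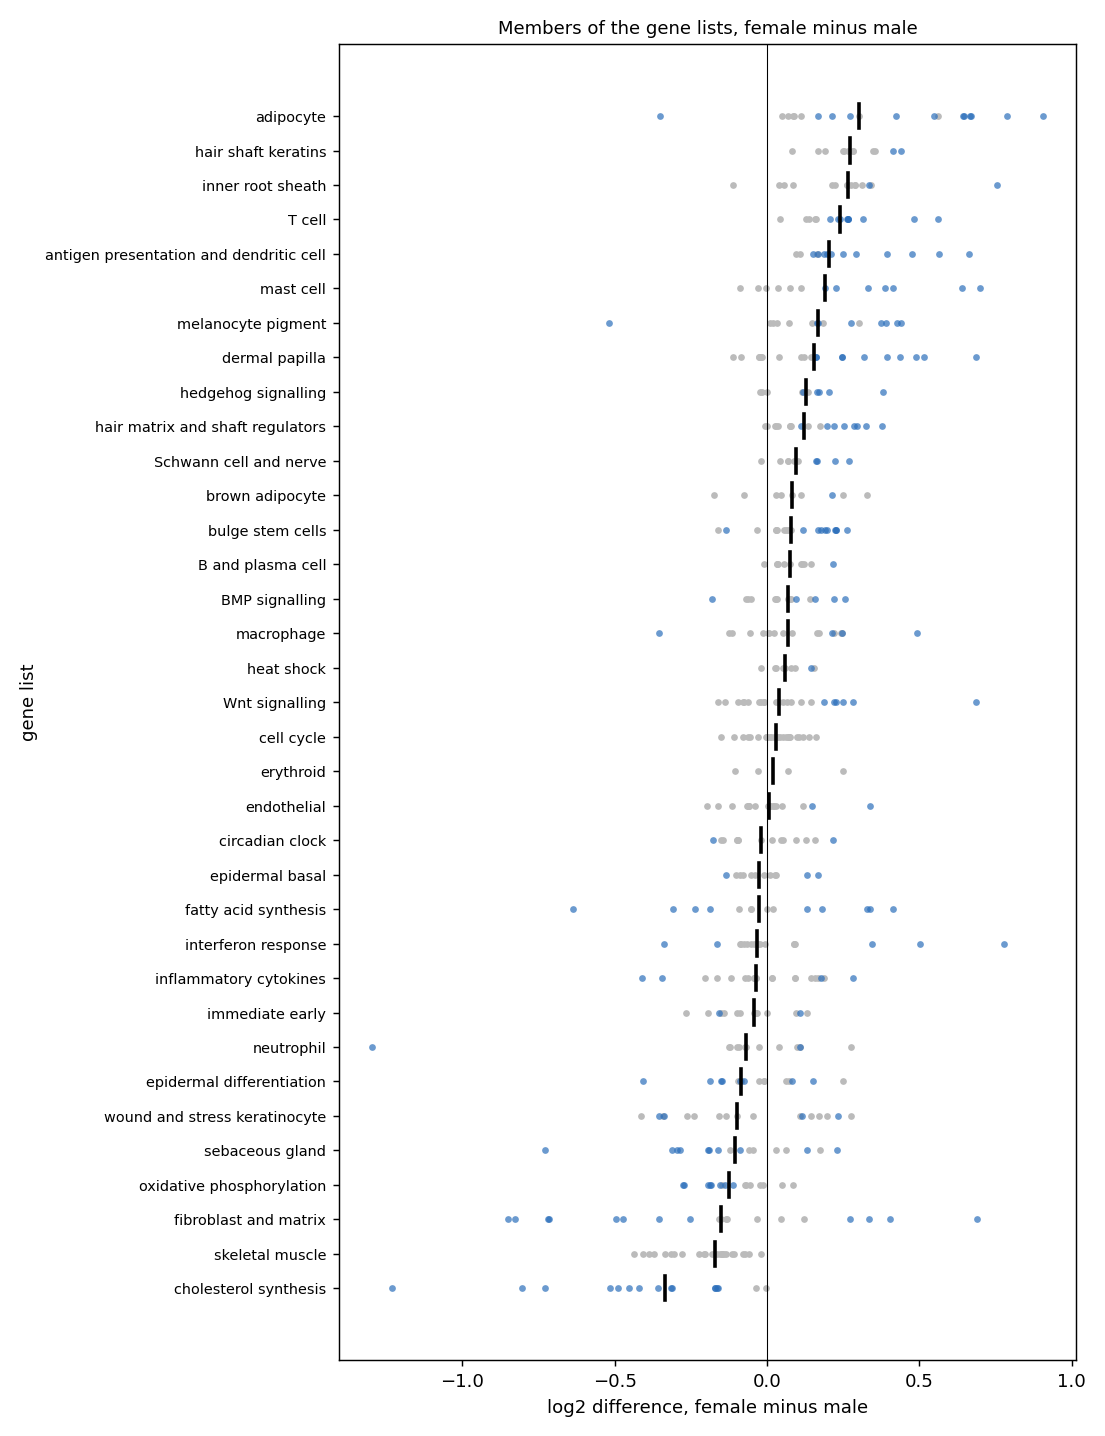
Female minus male difference (log2, x axis) of each member of 35 gene lists (y axis), each dot a gene, blue at an adjusted p under 0.05 and grey otherwise, with the list's median as a black bar. Cholesterol synthesis genes lie to the left (median -0.34) and adipocyte genes to the right (0.30).

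Camera did not call the other lists by sex, and 21.3% of all genes were called by sex in limma. Hair shaft keratins had 2 of 12 higher (median 0.27, adjusted p = 0.0702), Krt39 (0.44) and Krt84 (0.41). The score of this list averaged -0.944 in telogen females and -1.005 in telogen males, and 2.58 and 1.57 in anagen. Its difference by sex thus lay mostly in anagen, where only 8 males were measured. The interaction of stage and sex for this list and the inner root sheath is given below. Inner root sheath genes had 2 of 16 higher in females (1 adjusted over the list alone, adjusted p = 0.137), Dsg4 (0.75) and Tchh (0.33). Schwann cell and nerve genes were higher in 4 of 10 cases (adjusted p = 0.0645), with Ncam1 (0.27), S100b (0.22) and Sox10 (0.16). Wnt signalling genes were higher in 6 of 23 (1 lower adjusted over the list alone; adjusted p = 0.527), with Sfrp1 (0.28) and Wnt5a (0.25). BMP signalling genes were higher in 4 of 15 with 1 lower (adjusted p = 0.421), Sostdc1 (0.26) and Bmp7 (0.22) higher and Id3 (-0.18) lower. Fatty acid synthesis genes were higher in 5 and lower in 4 of 14 cases (5 lower adjusted over the list alone; adjusted p = 0.0628), with Acacb (-0.64, SE 0.056) lower and Thrsp (0.41) and Fads2 (0.34) higher. Macrophage genes were higher in 3 and lower in 1 of 18 cases (adjusted p = 0.571), with Lyz1 (0.49) and Aif1 (0.25) higher and Fcgr3 (-0.36) lower. In the neutrophil list of 13 Mpo was far lower (-1.29, SE 0.13) and Elane slightly higher (0.11; adjusted p = 0.0687). Interferon response genes were higher in 3 and lower in 2 of 18 cases (adjusted p = 0.421), with Cxcl9 (0.78), Cxcl10 (0.50) and Gbp2 (0.34) higher. Their median of -0.03 and mean of 0.05 differ in sign. Inflammatory cytokine genes were higher in 2 and lower in 2 of 22 cases (adjusted p = 0.24), with Tslp (-0.41), Cxcl2 (-0.35) and Il33 (0.28).

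Wound and stress keratinocyte genes were higher in 2 and lower in 2 of 17 cases (adjusted p = 0.363), with Stfa3 (-0.36) and Defb3 (-0.34) lower and Sprr1a (0.23) higher. Epidermal basal genes were higher in 2 and lower in 1 of 12 (adjusted p = 0.291), with Cdh3 (0.17), Trp63 (0.13) and Col17a1 (-0.13). Endothelial genes were higher in 2 of 18 cases, Angpt2 (0.34) and Apln (0.15), with a median of 0.0064 and a camera direction of down (adjusted p = 0.505). The median's sign changed when the arrays were rescaled. Brown adipocyte genes had 1 of 9 higher (2 adjusted over the list alone; adjusted p = 0.369), Ppargc1a (0.21). B and plasma cell genes had 1 of 11 (adjusted p = 0.241), Blk (0.22). Heat shock genes had 1 of 9 (0 adjusted over the list alone; adjusted p = 0.299), Bag3 (0.14). Circadian clock genes had 1 higher, Nfil3 (0.22), and 1 lower, Bhlhe40 (-0.18), of 15 (adjusted p = 0.241). Immediate early genes had 1 higher, Jun (0.11; 0 adjusted over the list alone), and 1 lower, Klf4 (-0.16), of 15 (adjusted p = 0.0706). Of 27 cell cycle genes 0 passed in limma and 1 had an unadjusted p under 0.05 (median 0.03, camera direction down, adjusted p = 0.915). Of 4 erythroid genes 0 passed, with 1 unadjusted (adjusted p = 0.98, a median of 0.02 that turned negative with arrays centred on their medians).

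Some hair genes rose more from telogen to anagen in females than in males. Krtap1-5 rose by 4.96 in females and by 3.28 in males, a difference between the sexes of 1.69 (SE 0.32, adjusted p = 0.0138), and Krtap6-3 by 5.87 and 3.90 (1.97, SE 0.42). The same direction held for Tchhl1 (1.45, SE 0.31), Prr9 (1.38, SE 0.32), Slc4a1 (1.29, SE 0.28) and Rims1, a synaptic vesicle gene (0.62, SE 0.13). Crabp1 fell by 1.35 in females and fell by 0.59 in males (difference -0.75, SE 0.19, adjusted p = 0.0409). Krtap1-5 averaged 4.21 in telogen females and 4.29 in telogen males, and 9.14 and 7.53 in anagen. In limma 61 genes had a stage difference that differed between the sexes, 30 more positive and 31 more negative in females, and 2511 had an unadjusted p under 0.05. After quantile normalization 29 of 42 and with centred arrays 31 of 39 were more positive. The hair shaft list had a median of 0.98 (camera, adjusted p = 8.38e-11, and adjusted p = 0.294 with an estimated correlation), in which 0 of 12 genes were called over all genes, 9 adjusted over the list alone and 10 unadjusted. Inner root sheath genes had a median of 0.89 (camera, adjusted p = 2.64e-07, and adjusted p = 0.816 with an estimated correlation), with 0 of 16 called, 5 higher and 1 lower adjusted over the list alone and 11 unadjusted. Only 8 anagen males stand behind the male difference. With each of them left out in turn, fits chosen after seeing the data, limma called from 0 genes (without replicate 5, 1931 at an unadjusted p under 0.05) to 297 (without replicate 21), and Krtap1-5 passed in 5 of 8 fits (1.19 to 2.06). With each of the 30 anagen females left out it called 26 to 100, and Krtap1-5 passed in 30 of 30. With each of the 28 pairs of anagen males left out the count ran from 0 to 756 with a median of 9.5, and the hair shaft median from 0.20 to 1.56. Of 3 anagen mice with a hair shaft score inside the telogen range, 2 were males (-0.32 in replicate 26 and -0.72 in replicate 32) and 1 was a female (0.16, replicate 37). Without them the hair shaft median was 0.33 (camera, adjusted p = 0.0589) and that of the inner root sheath 0.19 (adjusted p = 0.292), but they were picked by the score itself, which builds in a smaller difference, and 1 telogen female alone sets the top of that range. Limma called 0 genes without batch P2 (1915 at an unadjusted p under 0.05), 0 without batch P4 (1610), 8 with the title prefix in the model and 1 with arrayWeights.

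Anagen was more frequent in females, of whom 30 of 70 (42.9%, 95% interval 31.1 to 55.3) were in that stage, against 8 of 60 males (13.3%, 5.94 to 24.6). The odds ratio was 4.82 (1.90 to 13.5; Fisher's exact test, two-sided, p = 0.000225), and sex permuted within batch gave p = 0.00027. In batch P1 6 of 19 females and 2 of 15 males were in anagen, in P2 9 of 15 and 0 of 18, in P3 7 of 19 and 4 of 13, and in P4 8 of 17 and 2 of 14. Anagen mice had a lower age label, 42.8 ± 2.76 (n = 38) against 43.8 ± 2.36 (n = 92), a difference of -1.05 (permutation p = 0.0325, two-sided, and 0.0333 within batch), which was -1.27, -0.69, -0.74 and -1.34 in P1 to P4.

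Along the age label, the prostaglandin- and progesterone-metabolizing Akr1c18 rose by 0.12 per unit (SE 0.034), the clock gene Per2 by 0.098 (SE 0.027), and the glucocorticoid-responsive genes Tsc22d3 by 0.091 (SE 0.021) and Zbtb16 by 0.085 (SE 0.021), with stage in the model. Lrrc15 (-0.14 per unit, SE 0.031), Dsg4 (-0.14, SE 0.030), Krtap6-1 (-0.13, SE 0.034) and Mmp11 (-0.12, SE 0.031) declined. At age labels 42 to 44 alone the slopes of Per2 (-0.017), Zbtb16 (-0.031) and Mmp11 (0.13) had the other sign. In limma 120 genes rose and 127 declined with the label, and 3069 had an unadjusted p under 0.05. With centred arrays 32.9% of 243 genes rose. Camera called circadian clock (median slope 0.03, 2 of 15 genes higher and 7 adjusted over the list alone), fatty acid synthesis (0.01, 1 of 14 and 4) and inflammatory cytokines (0.0084, 0 of 22 and 5, with 8 unadjusted) up, with adjusted p of 0.0172, 0.0228 and 0.0149. Down were the lists of bulge stem cells (-0.02, 1 of 19 lower and 4 adjusted over the list alone), hair shaft keratins (-0.02, 2 of 12 and 2), fibroblast and matrix (-0.01, 0 of 19 and 0, with 5 unadjusted), melanocyte pigment (-0.02, 0 of 15 and 2, with 3 unadjusted) and oxidative phosphorylation (-0.0086, 0 of 16 and 0, with 1 unadjusted). Their adjusted p, in that order, were 0.000765, 0.00478, 0.00478, 0.00918 and 0.00918. With an estimated correlation adjusted p ran from 0.533 to 0.669, so that camera called 0 of the 37 lists (1 at an unadjusted p under 0.05), and fry called 0. Limma called 0 genes in females alone (1186 at an unadjusted p under 0.05), 200 in males alone, 0 at age labels 42 to 44 (737), and 743 with the title prefix in the model.

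Anagen mice varied more from each other in hair genes than telogen mice did. The SD of the hair shaft score, with sex and batch removed, was 1.07 in anagen (n = 38) and 0.198 in telogen (n = 92), a ratio of 5.37. Hair keratins sit near the bottom of the scale in telogen (Krt33a averaged 4.39, against a 25th percentile of gene means of 4.33), which can narrow their spread there. Inner root sheath (5.48), hair matrix (3.01), melanocyte pigment (2.30), erythroid (1.91) and fatty acid synthesis scores (1.38) also spread more widely. Brown adipocyte (0.559) and X gene scores (0.622) spread less. These 8 of 37 lists passed by permutation of the stage label, with a smallest adjusted p of 0.000925. With the median absolute deviation in place of the SD 4 of the 37 lists passed. Of the 8 these were hair shaft, inner root sheath and hair matrix alone. The other was skeletal muscle, which spread less in anagen (ratio 0.460, permutation adjusted p = 0.0324) and was not among the 8. Of 4 relations between scores tested, hair shaft and cell cycle scores were unrelated within telogen (r = 0.0055, rho = 0.0171, permutation p = 0.957 and 0.870) and within anagen (r = 0.118, rho = 0.0555, p = 0.473 and 0.739). Within batches r ran from -0.197 to 0.0949 in telogen and from -0.103 to 0.327 in anagen, and without the 2 mice farthest from the median it was -0.0402 and 0.0877. Skeletal muscle and adipocyte scores rose together in telogen (r = 0.472, rho = 0.463, permutation p = 1e-05 for each, the smallest that 100000 resamples give, adjusted p = 4e-05). Pearson's r was 0.462 without the 2 farthest mice and 0.495, 0.601, 0.626 and 0.133 in P1 to P4. In anagen they did as well (r = 0.462, rho = 0.462, permutation p = 0.00333 and 0.00349, adjusted p = 0.00666 and 0.00698), with 0.411 without the 2 farthest. Within batches of anagen mice r was 0.781 in P1 (n = 8, exact p = 0.0164), 0.311 in P2 (n = 9, exact p = 0.434), 0.116 in P3 and 0.490 in P4. By Pearson's r the relation thus passed in 1 of 4 batches in anagen, and in telogen it did not pass in P4. Spearman's rho in P1 of anagen was 0.714 (exact p = 0.0576), which does not pass.

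For 9 genes the mice fell into separate high and low groups. The complement receptor gene Cr2 was split most clearly, with levels 4.11 apart (12.5 pooled SDs) and 59 of 130 mice in the high group. Cwc22 (2.96), Plscr4 (2.56), the class II histocompatibility genes H2-Ea (3.12) and H2-Eb1 (2.77), Izumo1 (2.04), Retsat (2.24) and the apolipoprotein genes Apoc2 (1.70) and Apoc1 (0.93) followed, with 38.5% to 46.2% of mice in the smaller group. H2-Ea and H2-Eb1 put 100% of mice on the same side, and so did Apoc1 and Apoc2. A limit of 5 pooled SDs gave 25 genes and 8 gave 5. Only Cwc22 had other probes on the array. Of these 7, 6 carried values identical to those of the first, and the remaining one gave the same 2 levels (8.71 pooled SDs apart) in 100% of mice. For the other genes no second probe could tell a difference in transcript from a mismatch of a probe to an allele.

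Batch and title prefix are not questions of the series but bear on the values. Limma's F-test called 4 genes by batch, Xist, Eif2s3y, Uty and Kdm5d, named after their values were seen. All 4 are sex-linked, and a batch adjustment made without sex as a covariate would leave such differences, which was not tested. Mice with the PLX prefix (n = 63) differed from those with LGX (n = 57) by little in many genes, 3366 higher and 1094 lower, from -1.37 in Snord118 to 0.58, with 4 genes lower by 2-fold or more. Small nucleolar RNA genes, chosen after their values were seen, were lower in 39 and higher in 3 of 55 cases (median -0.35). Skeletal muscle genes were lower in 13 of 24 cases (22 adjusted over the list alone; median -0.77, camera adjusted p = 8.91e-09, and adjusted p = 0.794 with an estimated correlation). Oxidative phosphorylation genes were lower in 8 of 16 cases with 1 higher (median -0.07, camera adjusted p = 0.00228, and adjusted p = 0.794 with an estimated correlation). Bulge stem cell genes were higher in 12 of 19 cases (13 adjusted over the list alone; median 0.14, camera adjusted p = 0.00228, and adjusted p = 0.794 with an estimated correlation). Camera called 3 lists up and 6 down, and with an estimated correlation 0 of the 37 (2 at an unadjusted p under 0.05), while fry called 12. Within P1 to P4 limma called 577, 195, 31 and 0 genes by prefix, the last with 1939 at an unadjusted p under 0.05.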

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

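The short RNA, age and held-out batch tests of the title prefixes, the muscle, scaling, dilution and score permutation tests of the lower gene lists in anagen, and the interaction with anagen mice left out were chosen only after the result was seen. The other tests below were fixed earlier, although the small nucleolar RNA genes were chosen after their values were seen.

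The stage difference of 61 genes differed between the sexes by limma's interaction term, and with it the difference of Krtap1-5 (1.69), Rims1 (0.62), Krtap6-3 (1.97), Slc4a1 (1.29), Tchhl1 (1.45), Prr9 (1.38) and Crabp1 (-0.75), female minus male. Camera also called the hair shaft keratins (median 0.98) and the inner root sheath genes (median 0.89) at its preset correlation, but not with an estimated one (adjusted p = 0.294 and 0.816), and 0 of 12 and 0 of 16 of their genes were called in limma over all genes (10 and 11 unadjusted). With each of the 8 anagen males left out in turn limma called 0 to 297 genes, with each of the 30 anagen females 26 to 100, and with each pair of anagen males a median of 9.5, so the count depends on which few males are measured. In 3 of 100 regroupings, the real one included, as many genes were called, and the highest other count was 459, many times the real one. That share is within the bound fixed for the test, but it was not adjusted over the counts tested in this way. Leaving out a single male took the count as low as 0, so chance is not excluded. A count of 459 in a random regrouping may come from a structure among the mice that the groups do not describe. Such a structure was not tested for, nor told apart from correlation between genes, which makes calls come in bursts. Of 20 other settings, Krtap1-5, Slc4a1 and Tchhl1 passed in 12 each and Rims1 and Krtap6-3 in 11 each.

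For the lists lower in anagen, the first pattern weighed, 11 of 100 regroupings called as many lists lower (9 in the real grouping, 12 in the highest other). In 29 of 100 as many were called higher (6, against 11), so that chance cannot be excluded for either count of lists at the preset correlation. For the scores of the lower lists it can, as 9 of 9 were lower in anagen (by 0.21 to 0.41, permutation p over the 37 lists at most 0.0022). Lists that camera did not call were lower by this test too. Among them were Wnt signalling and Schwann cell and nerve (permutation p = 1e-04 each), mast cell (0.0003) and interferon response (0.0264). Skeletal muscle did not pass (permutation p = 0.167). The score test therefore does not set the 9 apart. Skeletal muscle in some samples does not account for 8 of the 9, which were called with the muscle score in the model; the endothelial list was not (adjusted p = 0.0966), its score difference going from -0.28 (SE 0.057) to -0.19 (SE 0.049), a smaller difference rather than a wider spread. Quantile normalization left 9 of 9 called, but it moved genes by little (SD of the shift 0.012) beside list medians of -0.44 to -0.25. It could hardly have removed a call. Centring shifts every gene alike, so the 9 of 9 called with it test nothing. For each of the 9 at most 0.69% of random gene sets of like mean level had a median as low. That goes against a scaling error that moves genes of like level alike. The 9 lists were picked for being lower than other genes, which builds in a part of this. A larger share of follicle RNA would lower every other cell type alike; the scores of 7 cell types moved apart, from -0.41 (SE 0.094) for macrophages to 0.20 (SE 0.063) for melanocytes (range 0.61, permutation p = 1e-04, the smallest that 10000 permutations give), and by 0.31 (p = 0.0204) without melanocytes, which sit in the follicle. Without adipocytes as well, whose genes went both ways, the range of the other 5 was 0.13 (p = 0.2563), so dilution stays open, as does a difference of the skin between the stages, which the design names and no test here isolates.

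Mice with the PLX prefix are the second pattern. Age does not account for the number of calls, as limma called 4856 genes with the age label in the model against 4460 without. The count does not show whether the same genes were called, or whether the small nucleolar RNA difference kept its size. A difference between batches does not account for the pattern, as genes called without a batch kept their sign in it (87.6%, 91.5%, 94.9% and 85.8% in P1 to P4) more often than in 95% of permutations in 4 of 4. The small nucleolar RNA median, below 0 in 4 of 4, cannot show this, since those genes were chosen for their values. A candidate explanation is a lower recovery of short RNAs, which stays undecided. The Snord (median -0.27) and Snora genes (-0.40) were chosen for their values and cannot support it, and the 6 Rnu genes were lower (-0.53). The 306 microRNA genes were not lower than random sets of like level (-0.0098, percentile 82). Their median level was 4.27, below the 25th percentile of gene means (4.33), against 6.71 for the Rnu genes. A difference can be compressed at so low a level, so the microRNA genes weigh little against a lower recovery. In the titles every LGX mouse carries a lower number than every PLX mouse. The prefix therefore cannot be told apart from whatever that order stands for. What the prefixes stand for is not given in the sources used here, and no biological explanation was tested.

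Genes at 2 separate levels are the third. It may be 1 inherited segment behind each pair of neighbouring genes, as H2-Ea and H2-Eb1 put 100% of mice on the same side and so did Apoc1 and Apoc2, while pairs other than these and Izumo1 with the Apoc genes shared at most 60.8%. The bound fixed for the test did not foresee Izumo1, which lies on the chromosome of the Apoc genes and shared 87.7% of mice with them, so the test stays undecided. A probe that matches only the allele of FVB/N or of M. spretus could give the same picture and cannot be told apart from a difference in transcript, since 1 of the 9 genes (Cwc22) had other probes. Of these 7, 6 carried identical values and the other gave the same 2 levels in 100% of mice (8.71 pooled SDs, r = 0.990), which goes against this explanation for Cwc22 unless its probes overlap; their positions are not in the files.

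For other counts, regroupings of the mice called at least as many genes in 1 of 100 for stage (10289, highest other 1) and in 1 for stage at 2-fold (304, highest other 0). The same held in 1 for sex (4011, highest other 19) and in 1 for the prefix (4460, highest other 3), so that chance can be excluded for these counts. Regroupings treat the mice as independent, whereas the LGX and PLX prefixes follow the order of the title numbers. For the prefix the regroupings therefore exclude only a random split of the mice. For sex, 3 of 100 called as many lists (17, highest other 20). For age 2 of 100 called as many genes (247), the highest other being 363, above the real count, and for batch 2 of 100 did (4, all sex-linked, highest other 16). These shares are within the bound fixed for the test, but they were not adjusted over the counts tested, and chance is not excluded by them. Regroupings called a median of 8 lists by sex, so a part of the 17 can be chance. The values carry the mark of a batch adjustment, so redrawn batches are not like the real ones and the share for batch decides nothing.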

How the results depend on the processing

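The skeletal muscle score as a covariate, the telogen-only comparisons of sex and age, the interaction with anagen mice left out and the prefix counts within batches were chosen after seeing the data. Of the 304 genes at 2-fold by stage, 303 had the same sign in P2 alone, 301 with the muscle score, 290 with the 25% dimmest genes left out, where genes left out do not count, and 304 in the other settings with 1 probe per gene or their mean. The 304 were picked in the same mice, so a shared sign is in large part built in. Stage calls stayed within 1.5 times the reported count in 19 of 24 settings, calls at 2-fold in 22 of 24, sex calls in 15 of 22, lists called higher in 23 of 25 and lower in 22 of 25, and lists by sex in 21 of 23. Interaction calls did so in 8 of 23 and age calls in 8 of 24. The share of mice in anagen by sex passed in the only other setting tried (1), and the age label by stage in both (2). These were permutations within batch or within sex and batch, and subsets of the mice were not tried. Arrays give no depth, and a gene near the background of its probes shows a compressed difference, which was not measured here. Where fewer mice or batches explain a lower count, this is by construction; for all other changes the cause was not tested.

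Stage calls numbered 3298 in males alone, 3643 in P1, 6191 in P2 and 3595 in P4, each with fewer mice, and 15871 with all probes, where more features were tested. At 2-fold there were 200 in males and 572 in P2. Sex calls numbered 594, 852, 242 and 639 in P1 to P4, 2306 without P4, 1618 at age labels 42 to 44 and 1250 in mice drawn to equal numbers of both stages.

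Interaction calls numbered 8 with the title prefix, 0 in P1 alone (574 at an unadjusted p under 0.05 in limma), 3 in P3 alone, 95 without P1, 0 without P2 (1915), 31 without P3, 0 without P4 (1610), 0 at age labels 42 to 44 (1406), 10 in drawn mice, 39 with centred arrays, 29 with all probes, 1 with arrayWeights and 2 without the 3 anagen mice inside the telogen range of the hair shaft score. These 3 were picked by the score itself, which builds in a smaller difference between the sexes, and 1 telogen female alone (0.28) sets the top of that range, the next telogen score being -0.39. The lowest count with an anagen mouse left out in turn was 0 (1931), and the median with each pair of anagen males left out was 9.5. In P2 the interaction could not be fitted, as it holds no anagen male.

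Age calls numbered 743 with the title prefix, 92 with no sex and batch term, 23 with batch as a random block, 0 in females (1186 unadjusted in limma), 200 in males, 0 in P1 (1688), 0 in P2 (1114), 0 in P3 (1161), 1 in P4, 1 without P1, 152 without P2, 35 without P3, 49 without P4, 0 at age labels 42 to 44 (737), 2 in drawn mice, 18 with arrayWeights and 4 in telogen mice alone.

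Lists called higher in anagen numbered 2 with an estimated correlation and 12 with fry. Lists called lower numbered 15 at age labels 42 to 44, 0 with camera at an estimated correlation (4 of 37 lists, in either direction, at an unadjusted p under 0.05) and 19 with fry. Lists by sex numbered 8 with trend and robust and 3 with an estimated correlation. Batch calls numbered 9 in telogen mice, and prefix calls 577, 195, 31 and 0 in P1 to P4 (1939 unadjusted in P4). Lists that differed in spread numbered 4 with the median absolute deviation. The relation of muscle and adipocyte scores did not pass in telogen in P4 (r = 0.133), or in anagen in P2 (0.311), P3 (0.116) and P4 (0.490). In anagen in P1 it passed by r but not by rho (0.714, exact p = 0.0576). Genes at 2 levels numbered 25 at 5 SDs and 5 at 8.

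Among named genes, Myh1 (0.051) and Pvalb (0.011) changed sign by stage with the muscle score in the model, which is fixed in part by their own place in that score, Alas2 (-0.13) in P2 alone, and Kdm5d (-1.26) without sex and batch, where more anagen mice are female. With the muscle score another 6 lost their call by stage, among them Cox8b (-0.087) and Alas2 (0.29). By sex, Krt84 (-0.082), Tchh (-0.11), Stfa3 (0.063), Awat1 (0.26), Bhlhe40 (0.13) and Jun (-0.10) changed sign in P2 alone, and Sfrp1 (-0.031), Sostdc1 (-0.0083), Tyrp1 (-0.013) and Dct (-0.040) in P3 alone. At age labels 42 to 44 the slopes of Per2 (-0.017), Zbtb16 (-0.031) and Mmp11 (0.13) did.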

Other observations

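The following sets of genes were chosen after their values were seen. Males were higher across a run of neighbouring imprinted genes that begins with Dlk1 and ends with Dio3. Meg3, a long noncoding RNA from the maternal chromosome, averaged 8.42 ± 0.45 (SD, n = 70) in females and 10.13 ± 0.52 (n = 60) in males, a difference of -1.58 (SE 0.081). Rian, a noncoding RNA of the same run, was at -0.86, and the microRNA genes Mir323 and Mir380 at -1.36 and -1.31. Of 42 measured genes among the 103 that the reference names there, limma called 38 lower and 1 higher in females, with a median of -0.45. The 36 microRNA genes of the run had a median of -0.45, and the 270 elsewhere a median of -0.0069, with 30 called lower. The protein-coding ends of the run did not follow, with Dlk1 at 0.25 (SE 0.052) and Dio3 at 0.02 (SE 0.083).

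Other families by name were looked at as well. Small nucleolar RNA genes were lower in females in 35 of 55 cases (median -0.21) and rose in anagen in 25 with 5 lower (median 0.12). Ribosomal protein genes were lower in females in 41 of 70 cases (median -0.09). By stage they were split, with 16 higher and 19 lower. Of 15 Lce genes, of the outer epidermis, 11 fell and 2 rose in anagen (median -0.41), and of 14 Sprr genes 8 rose and 1 fell (median 0.18).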
